A study of Mus musculus with 13 samples.

How the data were processed

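ChIP-seq peak lists of mouse limb tissue at E12.5 were analysed: 7 of CTCF (3 wild type, 4 homozygous HoxD deletion alleles), 3 of RAD21 and 1 of SMC1. The series holds 13 samples; the 2 H3K27ac samples, in wild-type distal and proximal forelimb, were not analysed here. Each group had 1 library, so there are no replicates and no p-values, and library and group cannot be separated. The CTCF library of del(8-13)rXII differs from wild type in assay (ChIPmentation) and tissue (forelimbs alone) as well as genotype, and per the labels the RAD21 library of this allele was sequenced in 2 runs. The labels name fixation of 10 minutes for CTCF, 10 or 25 minutes for RAD21 and 25 minutes for SMC1, without giving the time of each RAD21 library.

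Per the submitters' processing notes, cutadapt (adapter trimming), Bowtie2 (alignment), MACS2 (peak calling) and build mm10 were used, with no versions given; what each tool does is general knowledge and not stated there. The deposited files are narrowPeak lists, 1 per sample, which hold the position and summit of each called region. Their score is the −log10 q times 10 as a whole number, as deposited by the authors. The fold enrichment is a ratio of the signal at the summit to the local background, computed by the authors. The −log10 p and −log10 q of each summit were likewise computed by the authors, and the lowest −log10 q of each list is at the level of a q of 0.05. These strengths depend on read depth, which is unknown, and were ranked within a list only. A −log10 q of at least 10, used as an alternative in all lists, is therefore not an equal cutoff: the median of the CTCF lists runs from 7.07 in del(8-13)rXII to 30.9 in del(8-13)d11lac.

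Rows of the same region with several summits were merged into 1 peak with its strongest summit, and chromosomes 1 to 19, X and Y were kept. Coordinates are 1-based, on GRCm38.p6 with GENCODE release M21, and no peak reached beyond the end of its chromosome. Peaks were shared when they overlapped by at least 1 bp, and shares were set beside the mean of 100 circular shifts of the peaks. Wilson 95% intervals cover counting error only.

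Consensus CTCF sites were whole-limb peaks that overlapped a distal and a proximal peak; for RAD21 the whole-limb peaks were used. Runs of consecutive sites without a mutant peak were compared with runs elsewhere and with 10000 shuffles of the missing sites within chromosomes. Sites and mutant peaks within 1 Mb of the widest interval were counted, as percentiles of genome windows with as many sites; a new CTCF peak overlapped no wild-type CTCF peak, and a new RAD21 peak no wild-type RAD21 or SMC1 peak. The number of kept sites given by strength uses the share kept in each of 20 equally filled bins of −log10 q.

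A CTCF motif matrix of 19 bp, started from the known core of the motif, was refined on the 2000 strongest whole-limb summits, and the best match within 50 bp of a summit was kept where its score passed 7.35 bits, the level that 5% of control windows 2 kb away passed. None of the 9 HoxD sites was strong enough to be among those summits.

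The 17 gene lists were written before the data were examined: the HoxD locus, the HoxA, HoxB and HoxC clusters, distal limb patterning, proximal limb patterning, forelimb and hindlimb identity, chondrogenesis, muscle, endothelium, blood, neural, surface ectoderm, housekeeping, imprinted clusters, protocadherin clusters, and the cohesin and CTCF machinery. Of the 20 genes of the HoxD locus list 18 were matched as protein-coding, of 21 imprinted genes 17 and of 19 protocadherin genes 18. Members with a peak within 10 kb, or with distal cohesin but no CTCF within 1 kb of the TSS, were counted and compared with 10000 random lists matched on gene length.

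Genes and sites were named by a rule set before the data were examined. It takes every consensus site in the lost interval and up to 10 of the strongest on each side, the genes nearest to the 10 strongest distal-only and proximal-only peaks with a TSS within 5 kb, the 20 genes at the strongest cohesin sites without CTCF, the 5 strongest sites missing elsewhere in each allele, and up to 4 members per list. Predicted genes were passed over. The weak Atf2 site, the retained and new peaks at HoxD, Hoxc13 and genes at whole-limb RAD21 sites without CTCF were named after their values were seen.

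The comparisons, thresholds and alternatives were also fixed at that point. Chosen after the data were seen were runs that pass over 1 kept site, flanks of the outermost lost sites, autosomes alone, shares by decile, sites with a −log10 q of at least 50, like strength as within a factor of 1.2, whole-limb RAD21 without CTCF, no CTCF peak within 1 kb of a cohesin peak, and peaks of a single forelimb part near the gene lists. The length of same-strand motif runs was also not among the comparisons fixed beforehand. The alternatives fixed in advance were a −log10 q of at least 10, at least 50% of the peak covered, summits within 200 bp, lists of equal length, flanks of 0.5 and 2 Mb, all whole-limb peaks as sites, motifs within 100 bp, unmatched random lists, and peaks within the gene.

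The steps were tested on simulated data. In 5 simulated mutant lists made from 43533 sites with 90% kept, 8 consecutive sites removed and 50 new peaks planted, the largest error of the kept share was 0 percentage points, all 5 removed stretches were found and at least 49 new peaks were recovered, while the longest chance run elsewhere held 6 sites. The kept peaks were wild-type peaks moved by a small distance, so the error of 0 was fixed in advance and checks the code alone. Sites were dropped at random, whereas loss in the real lists followed strength, so the chance run does not carry over to them. The strand of planted motifs was recovered in 99.8% of 1000 sequences, and 20 lists of 15 genes planted with whole-limb RAD21 without CTCF at each TSS reached percentile 100. The 20 random lists of that test had a median percentile of 30.3 and a mean of 45.9, with few genes carrying such a peak. For distal CTCF peaks within 10 kb, 200 random lists had a median of 47.8 and 200 planted lists a median of 97.5, from 90.0 to 99.6, because 80.1% of all genes have such a peak. For proximal peaks the medians were 51.6 and 97.2. For distal-only and proximal-only peaks random lists had medians of 51.7 and 52.1 and all planted lists reached at least 99.99. Of 200 random lists each, 9 stood at percentile 95 or above for distal, 7 for proximal, 19 for distal-only and 11 for proximal-only peaks, so that percentile alone sets little apart. Overlaps were checked with bedtools 2.31.1, which counted the same 57415 shared distal CTCF peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.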

Results

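Chromatin-bound CTCF and the cohesin subunits RAD21 and SMC1 were profiled in limb tissue of mouse embryos at E12.5. CTCF is a zinc-finger protein that binds an oriented DNA motif, and cohesin is the ring-shaped complex that extrudes chromatin loops and is held up at CTCF sites. The HoxD cluster on chromosome 2 holds a series of homeobox genes that pattern the limb axes, between a centromeric and a telomeric regulatory landscape. The series title places a domain boundary at this cluster, and the design text names a series of HoxD deletions, so the questions are which CTCF and cohesin sites each allele lacks and whether sites around it change. Peak lists from 11 libraries were used, with 1 library per group. Wild-type CD1 embryos gave CTCF lists from distal and from proximal forelimb, and RAD21 and SMC1 lists from distal forelimb. Wild-type B6CBAF1 embryos gave CTCF and RAD21 lists from pooled whole forelimbs and hindlimbs. Homozygous embryos of 4 alleles, named del(8-13)d11lac, del(8-13)rXII, del(1-13)d9lac and del(attP-Rel5)d9lac, gave a CTCF list each, and del(8-13)rXII also a RAD21 list. By their names the first 2 lack the genes from Hoxd8 to Hoxd13 and the next lacks those from Hoxd1 to Hoxd13, while d11lac and d9lac name lac reporters. The CTCF library of del(8-13)rXII was made by ChIPmentation, in which a transposase adds the adapters on the beads, and from forelimbs alone. The lists held from 15927 peaks (RAD21 in del(8-13)rXII) to 73682 peaks (CTCF in proximal forelimb). Read depth is unknown, so a missing peak means that none was called, and no difference between libraries below has a replicate check. Intervals are Wilson 95% intervals and cover counting error only.

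In wild-type limbs the HoxD cluster carried 9 consensus CTCF sites, that is, whole-limb peaks that overlapped a peak in both the distal and the proximal forelimb list. They spanned 61.1 kb of chromosome 2, from 74655315 to 74716372 (mm10, as all coordinates here), from Evx2, a homeobox gene next to the cluster, to the introns shared by Hoxd3 and Hoxd4. The site at 74655315 to 74655721 lay in a UTR of Evx2, and those at 74661629 to 74662138 and 74663558 to 74663930 lay between Evx2 and Hoxd13, the gene needed for digit patterning. The site at 74672984 to 74673330 was intergenic between Hoxd13 and Hoxd12. The site at 74686323 to 74686684 lay in an exon of Hoxd11, outside its annotated coding sequence and UTRs, and that at 74694024 to 74694427 in a coding exon of Hoxd10. An intergenic site at 74691608 to 74691923 had its summit 155 bp before the start of Hoxd10. The last pair lay between Hoxd9 and Hoxd8 (74702212 to 74702605) and in an intron of both Hoxd4 and Hoxd3 (74715703 to 74716372). By the authors' −log10 q in the whole-limb list, the strongest was the Hoxd9 to Hoxd8 site at 60.4 (percentile 86.0 of that list), followed by those in Hoxd11 (56.8), between Hoxd13 and Hoxd12 (54.1) and in Hoxd4 (53.4).

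The CTCF motifs were on the minus strand from Evx2 to Hoxd12, mixed across Hoxd11 and Hoxd10, and on the plus strand from Hoxd9 to Hoxd4. A motif passed the score threshold at 7 of the 9 sites, 4 on the minus strand and 3 on the plus strand. Minus-strand motifs stood in Evx2 (CTGCCGCTAGGGGGCGCCC, 74655523 to 74655541), at the Evx2-proximal intergenic site (AAAACAGATGGGGGCGCCA, 74661997 to 74662015), between Hoxd13 and Hoxd12 (CGCCCAGGAGATGGCGAGC, 74673174 to 74673192) and in Hoxd10 (TGATCTCTAGGCGGCGCTC, 74694225 to 74694243). Plus-strand motifs stood in Hoxd11 (CAGCCACACGAGGGCGCGC, 74686477 to 74686495), between Hoxd9 and Hoxd8 (TGGCCACTAGAGAGCGCTG, 74702392 to 74702410) and in Hoxd4 (TGTCCAGGAGGAGGCGCTG, 74715918 to 74715936). On the telomeric side, 11 of the 15 sites within 1 Mb had a minus-strand motif and 2 a plus-strand motif, and 10 of these minus-strand motifs followed each other without a plus-strand motif between. Of 16544 same-strand runs in the genome, 37 (0.224%) were at least as long, and the longest held 34 sites. Over the genome 51.9% of neighbouring consensus sites shared a motif strand. This comparison was not fixed beforehand. It sets the longest run of 1 flank beside all runs, short ones included, so the share does not measure how rare such a flank is. On the centromeric side 7 of 14 sites had a plus-strand and 5 a minus-strand motif. These orientation counts rest on a motif within 50 bp of the summit. With motifs within 100 bp the centromeric side had 6 on each strand.

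**Figure D1:**
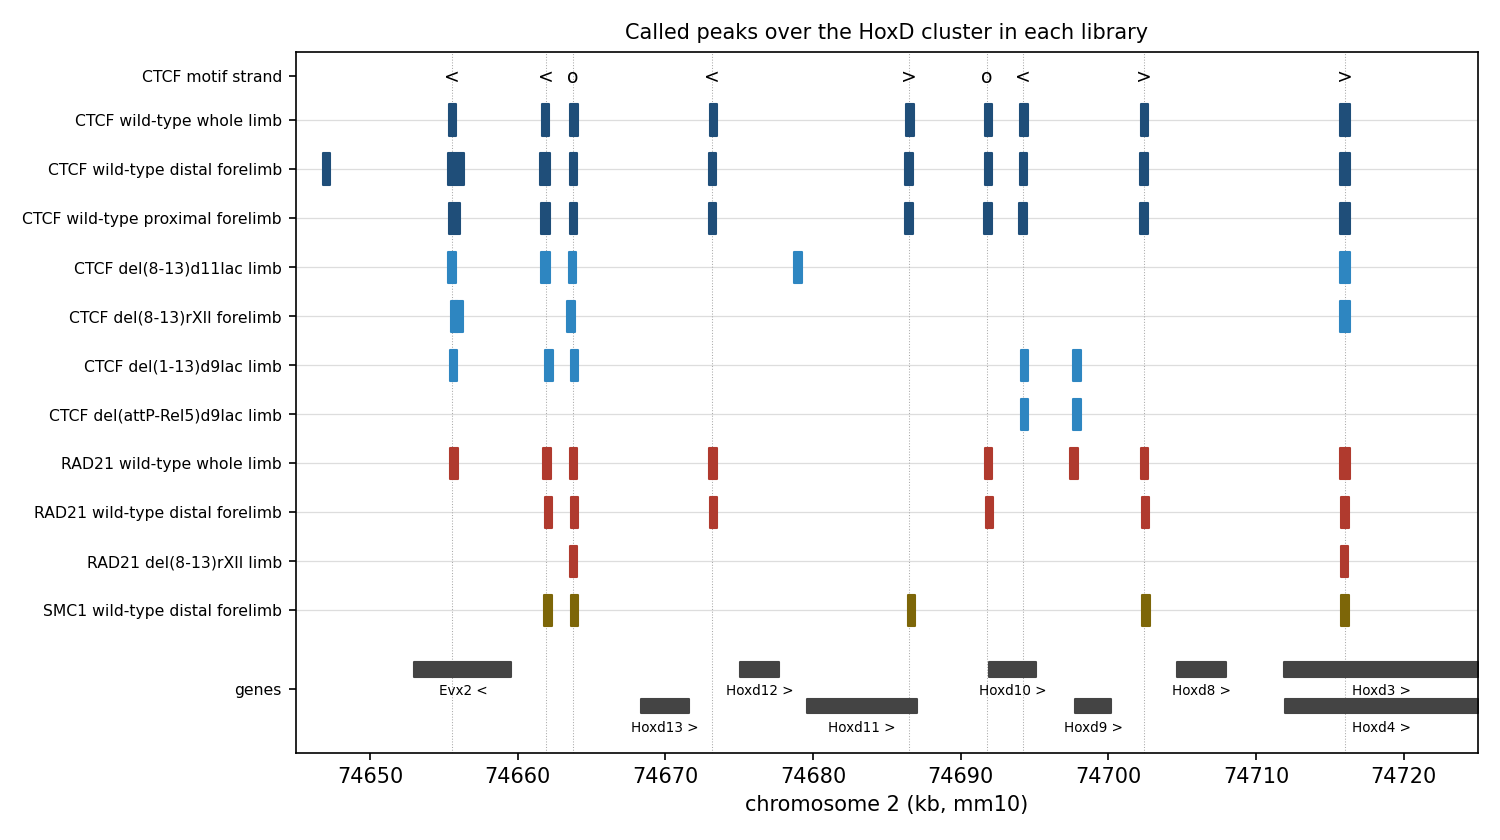
Map of called peaks over the HoxD cluster (horizontal axis: chromosome 2 position in kb, mm10), 1 row per library, with genes as dark bars below and their strands as arrowheads. Each coloured block is a called peak; the top row gives the motif strand at the 9 wild-type consensus CTCF sites (> plus, < minus, o none passing). The d9lac alleles hold a peak in Hoxd10 and at Hoxd9, inside the lost interval.

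Each allele lacked a block of these CTCF sites. In del(8-13)d11lac 5 of the 9 sites had no peak, a single unbroken run of 29.6 kb from 74672984 to 74702605 that covered the sites between Hoxd13 and Hoxd12, in Hoxd11, before and in Hoxd10, and between Hoxd9 and Hoxd8. The Evx2 and Hoxd4 sites on its edges were kept. In del(8-13)rXII the same 5 sites were missing, together with the Evx2-proximal intergenic site at 74661629, so that 6 had no peak. The site at 74661629 was weak in wild type (−log10 q 11.9), and a kept site lay between it and the other 5. Of 4164 sites of like strength, 29.8% also had no peak in this list. In del(1-13)d9lac 5 sites were missing, now including the Hoxd4 site, and the 3 sites in and beside Evx2 were kept. In del(attP-Rel5)d9lac 8 of the 9 were missing, and the retained one was the site in Hoxd10. Both d9lac alleles kept that Hoxd10 site, which del(8-13)d11lac and del(8-13)rXII lacked, with a −log10 q of 26.3 in del(1-13)d9lac and 35.0 in del(attP-Rel5)d9lac. Kept means here that a peak was called, not that the sequence stayed in its place. The blocks are bounded by consensus sites alone. In del(attP-Rel5)d9lac the nearest kept ones beyond the loss ended at 74306048 and started at 74964306, so the loss may reach past the 9 sites. A distal CTCF peak between Lnpk and Evx2 (74635471 to 74635787, −log10 q 19.8) was absent from the whole-limb list. A peak overlapped it in del(8-13)d11lac (16.1) and del(1-13)d9lac (5.16), but not in del(attP-Rel5)d9lac or del(8-13)rXII.

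Each lac allele also showed CTCF signal inside the interval where no wild-type CTCF list had a peak. Both d9lac alleles had a peak over the start of Hoxd9, at 74697631 to 74697898 in del(1-13)d9lac (−log10 q 6.84) and at 74697628 to 74698137 in del(attP-Rel5)d9lac (14.97). In del(8-13)d11lac a peak stood at 74678720 to 74678965 (12.4), 592 bp before Hoxd11. The list of del(8-13)rXII had no such peak.

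In 3 of the 4 alleles, the strong sites without a peak all lay at HoxD. Of 8336 wild-type consensus sites with a −log10 q of at least 50, a limit chosen after the values were seen, 3 had no peak in del(8-13)d11lac, 4 had none in del(1-13)d9lac and 4 had none in del(attP-Rel5)d9lac, each of them in the HoxD interval. In del(8-13)rXII 22 of these sites had no peak, 3 at HoxD and 19 elsewhere, the strongest of which was nearest to Arid1b, a chromatin remodeller gene (17, 4626053 to 4626715, −log10 q 214), followed by those nearest to Prh1 (101.2), Mydgf (91.8), Sulf1 (91.1) and Mid1 (90.4). The gene with the nearest TSS can be far away: 367958 bp for Arid1b and 305099 bp for Mid1, against 16126 bp for Mydgf. The names give a place and no target. The strongest missing sites outside HoxD in del(8-13)d11lac were nearest to Batf3 (30.9), Tbc1d23, Gabrp, Nudt6 and Dnah7b (18.5). Those of del(1-13)d9lac were nearest to Batf3 (30.9), Ipo8, Tmppe, Ccdc69 and Olfr1324 (24.9), and those of del(attP-Rel5)d9lac to Vamp9 (30.8), Zkscan2, Srpx, Olfr1324 and Ebf2 (22.1). Some of these sites lacked a peak in several alleles: the Nudt6 site in all 4, the Dnah7b site in 3, and the Batf3, Tbc1d23, Gabrp, Srpx and Ebf2 sites in 2 each, so that none of the 5 named for del(8-13)d11lac was missing in that allele alone. Over consensus sites of any strength, 98.7% of 39477 had a peak in del(8-13)d11lac, 90.4% in del(attP-Rel5)d9lac, 87.2% in del(1-13)d9lac and 77.0% in del(8-13)rXII. The loss fell with strength: the weakest decile of whole-limb peaks was kept in 47.6% in del(8-13)d11lac and 11.4% in del(8-13)rXII, and the strongest in 100% and 99.7%.

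As an unbroken run of missing sites, which was the measure fixed before the data were examined, HoxD gave 5 sites in del(8-13)d11lac, 5 in del(8-13)rXII, 3 in del(1-13)d9lac and 6 in del(attP-Rel5)d9lac. The retained Hoxd10 site splits the run in the d9lac alleles; passing over 1 kept site, a rule added after seeing the data, gave 5, 6, 5 and 8. No autosomal run elsewhere was as long as the unbroken HoxD run in del(8-13)d11lac or del(attP-Rel5)d9lac, while 33 were in del(8-13)rXII and 88 in del(1-13)d9lac. The longest runs elsewhere held 10 sites (del(8-13)d11lac) and 8 sites (del(attP-Rel5)d9lac) on chromosome Y, 7 on chromosome X (del(1-13)d9lac) and 12 on chromosome 14 (del(8-13)rXII). The longest run in 10000 shuffles of the missing sites within chromosomes had a median of 3, 7, 5 and 4 sites in del(8-13)d11lac, del(8-13)rXII, del(1-13)d9lac and del(attP-Rel5)d9lac. Its highest value over the shuffles was 9, 15, 9 and 9 sites, longer than the unbroken HoxD run in each allele. The shuffled runs were taken over all chromosomes, X and Y included, and were not repeated for autosomes alone. Since the longest real runs of 3 alleles lay on X or Y, these values do not tell how long a shuffled autosomal run gets. The median −log10 q of the unbroken HoxD run in del(8-13)d11lac was 54.1, against at most 6.70 for any other autosomal run of 3 or more sites in that allele. The same values were 54.1 against 22.8 in del(8-13)rXII, 54.1 against 15.7 in del(1-13)d9lac and 28.5 against 9.44 in del(attP-Rel5)d9lac.

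Beside HoxD most wild-type CTCF sites kept a peak in each allele, and all those without one were weak (−log10 q of at most 12.1). For del(8-13)rXII this depends on the threshold: in the flanks fixed beforehand, which reach into the deleted genes, 22 of 32 sites (68.8%) kept one with the lists as deposited, and 8 of 24 (33.3%) with a −log10 q of at least 10 in all lists. That value is a stricter cutoff in the list of del(8-13)rXII, with a median −log10 q of 7.07, than in the other CTCF lists, with medians from 16.1 to 30.9. Within 1 Mb of the outermost lost sites there were 29 consensus sites, 14 centromeric and 15 telomeric. Of these, 28 (96.6%, 82.8 to 99.4) had a peak in del(8-13)d11lac, 27 (93.1%, 78.0 to 98.1) in del(attP-Rel5)d9lac, 25 (86.2%, 69.4 to 94.5) in del(1-13)d9lac and 21 (72.4%, 54.3 to 85.3) in del(8-13)rXII. The genome-wide rates for sites of the same strength give 28.8, 26.8, 26.0 and 23.4 sites in that order. All 15 telomeric sites were kept in each of the alleles except del(8-13)rXII, which kept 12. The strongest flanking site, at 75605703 to 75606099 before Hnrnpa3 (−log10 q 125), and the site telomeric to Mtx2 at 74964306 to 74964735 (51.0), had a peak in all 4 alleles, as did the strongest centromeric sites, at 74066645 to 74067012 (53.4) and 74300284 to 74300624 (48.2) between Atp5g3 and Lnpk. The 10 strongest telomeric and the 7 strongest centromeric sites had a peak in every allele. A weak site in an intron of Atf2, at 73867814 to 73868003 (5.36), lacked a peak in all alleles but del(8-13)rXII. The kept shares stood at percentiles 17.3, 64.6, 40.8 and 27.4 of genome windows with as many sites, in the order del(8-13)d11lac, del(attP-Rel5)d9lac, del(1-13)d9lac and del(8-13)rXII. These flanks were set after seeing the data; in the flanks of the unbroken run, fixed beforehand, 29, 28, 26 and 22 of 32 sites had a peak, at percentiles 0.605, 27.9, 17.7 and 14.9.

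New CTCF peaks beside HoxD were few with the lists as deposited. Of the mutant peaks within 1 Mb of the outermost lost sites, 4 of 55 (7.27%) in del(8-13)d11lac, 1 of 25 (4.00%) in del(8-13)rXII, 1 of 35 (2.86%) in del(1-13)d9lac and 0 of 37 in del(attP-Rel5)d9lac overlapped no wild-type CTCF peak. The shares over the genome were 7.08%, 4.62%, 5.19% and 2.94%. The strongest of these new peaks, in del(8-13)d11lac at 75528585 to 75528827, had a −log10 q of 6.94. With the flanks fixed beforehand the counts were 4, 1, 2 and 1, the added ones being the peak at Hoxd9 in each d9lac allele. In those flanks lists of equal length, which drop weak peaks of the longer lists, gave 2, 3, 7 and 6.

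**Figure D2:**
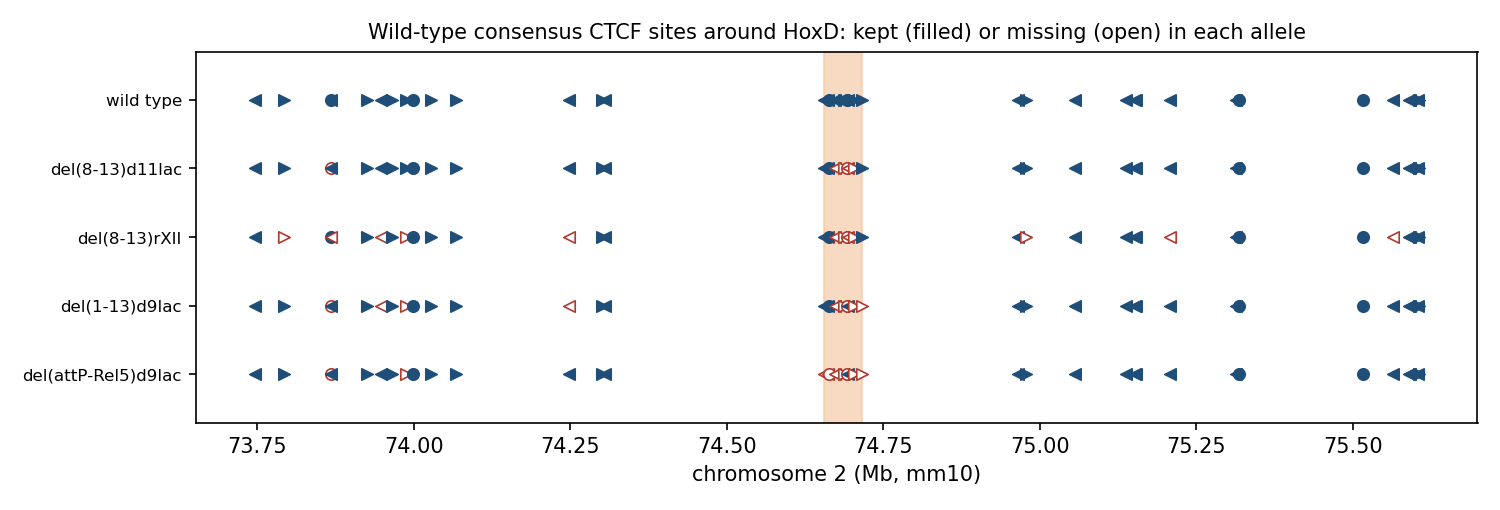
Wild-type consensus CTCF sites within 1 Mb of HoxD (horizontal axis: chromosome 2 position in Mb, mm10), 1 row for wild type and 1 per allele. Filled markers have a called peak and open markers have none; triangles point along the motif strand, circles have no passing motif, and the shaded band is the interval from 74655315 to 74716372. Most open markers lie inside the band.

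RAD21 at HoxD was lost over the same genes as CTCF in del(8-13)rXII. Wild-type whole limbs had RAD21 peaks at the Hoxd4 site (74715712 to 74716368, −log10 q 159), at both sites between Evx2 and Hoxd13 (74661724 to 74662200, 89.6, and 74663505 to 74663935, 67.6), and at weaker sites in Evx2, between Hoxd13 and Hoxd12, before Hoxd10, at Hoxd9 and between Hoxd9 and Hoxd8. In del(8-13)rXII the Hoxd4 site (52.5) and the intergenic site nearer Hoxd13 (16.1) were kept. The run from 74672959 to 74702612 with its 4 wild-type sites had no peak, and neither had the site at 74661724, the second strongest RAD21 site of the cluster. All 3199 wild-type whole-limb RAD21 peaks elsewhere that were at least as strong as the latter had a peak in del(8-13)rXII. The site in Evx2 also had none, but it was weak (−log10 q 9.52), and 18.8% of wild-type peaks in its decile had a peak in del(8-13)rXII. Within the run the Hoxd9 site was weak too (−log10 q 6.25), and 8.31% of wild-type peaks in its decile had a peak in del(8-13)rXII. Over all 33707 wild-type peaks only 45.2% had one, and the longest missing run elsewhere held 50 sites on chromosome Y, so run length alone does not set HoxD apart for RAD21.

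Beside HoxD, 17 of 23 wild-type RAD21 sites (73.9%, 53.5 to 87.5) had a peak in del(8-13)rXII, where the rates for their strength give 14.4, and no mutant peak of 17 was new, against 3.51% over the genome. With the flanks fixed beforehand 18 of 25 sites (72.0%, 52.4 to 85.7) were kept and 0 peaks of 18 were new. The kept share of the 23 sites stood at percentile 98.9 of genome windows with as many sites.

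Not all CTCF sites of the cluster carried cohesin. The strong CTCF site in Hoxd11 and the one in Hoxd10 had no RAD21 peak in whole limbs or in distal forelimb, and SMC1 was called at the Hoxd11 site with a −log10 q of 3.47. Among whole-limb CTCF peaks of like strength, within a factor of 1.2 in −log10 q, 12.54% (11.6 to 13.5) lacked RAD21 at the level of the Hoxd11 site and 23.9% (22.7 to 25.2) at that of the Hoxd10 site. In distal forelimb the shares were 21.9% and 41.8%. The Evx2 site also had neither a RAD21 nor a SMC1 peak in distal forelimb, where 30.6% (29.5 to 31.8) of CTCF peaks of like strength lacked RAD21, but it had a weak RAD21 peak in whole limbs (−log10 q 9.52).

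CTCF sites were largely common to distal and proximal forelimb, the parts that form the digits and the arm. Of 69495 distal peaks, 82.6% (82.3 to 82.9) overlapped a proximal peak, and 77.8% (77.5 to 78.1) of 73682 proximal peaks overlapped a distal one, against 2.16% and 2.05% after shifting the peaks along their chromosomes. Whole-limb peaks overlapped a distal peak in 91.9% (91.7 to 92.2) and a proximal peak in 92.0% (91.8 to 92.3). In the strongest 4 deciles of distal peaks the shared share was 100%, and in the weakest it was 27.6%. At HoxD the 9 consensus sites were present in both tissues by definition, and the strongest in both was the Hoxd9 to Hoxd8 site (−log10 q 188 distal, 183 proximal). The tissues come from the same strain, and the 2 lists were called separately.

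Peaks in a single forelimb part were weak. The 11047 distal peaks with no proximal peak within 1 kb had a median −log10 q of 4.38, against 37.0 for shared distal peaks, and 42.3% (41.4 to 43.2) had a CTCF motif, against 83.8% (83.5 to 84.1). The 15145 proximal peaks with no distal peak within 1 kb had a median of 3.95 and a motif in 36.6% (35.9 to 37.4). The strongest distal-only peaks near a TSS stood at Cdx4 (−log10 q 25.2), Pcdhga12 (22.1), a clustered protocadherin, Sema6a (22.0), Rcc2 (21.6), Baiap2l2 (21.4), Meis1 (20.0), a homeobox gene that marks the proximal limb, Ssh2 (19.5), Hoxa13 (19.5), which patterns the digits together with Hoxd13, Plec (19.1) and Yy1 (19.02), a zinc-finger factor. The Hoxa13 peak lay on chromosome 6 at 52264842 to 52265131, outside the gene. The strongest proximal-only peaks near a TSS stood at Snapc2 (23.9), Shpk (20.8), Zfp949 (20.4), Me1 (20.3), Strn (19.5), Rph3al (18.3), Igf1r (18.0), the receptor of insulin-like growth factors, Cstf2 (16.3), Ugdh (16.2) and Cyp4f39 (15.8). No limb patterning gene was among these 10.

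Nearly all cohesin peaks of distal forelimb lay on CTCF. A CTCF peak overlapped 96.6% (96.3 to 96.8) of the 16498 RAD21 peaks and 94.0% (93.6 to 94.3) of the 23185 SMC1 peaks, against 1.79% of RAD21 and 1.78% of SMC1 peaks after shifting. RAD21 and SMC1, subunits of one complex, also coincided, with a SMC1 peak at 87.9% (87.4 to 88.3) of RAD21 peaks. In the longer SMC1 list 62.5% (61.9 to 63.1) of peaks had a RAD21 peak. Conversely, 20.6% (20.3 to 20.9) of the distal CTCF peaks had both subunits. That share rose with CTCF strength from 0.532% in the weakest decile to 79.8% in the strongest. With the lists shortened to the same length, 70.0% of RAD21 peaks had CTCF.

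With the lists as deposited, few cohesin sites of distal forelimb lacked CTCF, and many of these lay at promoters. In all, 76 sites had RAD21 and SMC1 and no peak in any wild-type CTCF list, and 34 of them (44.7%, 34.1 to 55.9) lay within 1 kb of a protein-coding TSS, where 8.67% (8.44 to 8.90) of the shared distal CTCF peaks lay. A CTCF motif was found at 8 of the 76. Of those within 1 kb of a TSS, the strongest by −log10 q in the SMC1 list stood at Ssbp2 (14.1), Cpped1 (9.29), Tbck (7.79), the mitochondrial ribosomal protein genes Mrps31 (7.19) and Mrpl1 (7.03), Robo2 (6.61), an axon guidance receptor, Cog6 (6.004), Ap3s2 (5.96), Mmadhc (5.77) and Cox10 (5.41). Gpc5, Rbms1, Gtf3c3, Hist4h4, Wdr36, Olfml2b, Smarcal1, Med13l, Stx18 and Ints4 completed the 20 genes, with values from 5.22 down to 3.96. The strongest of all 76 reached 20.5 and stood at none of these genes. A CTCF peak that did not overlap lay within 1 kb of 22 of the 76 sites, among them those at Hist4h4, Wdr36 and Ints4, and without these 22 the share at a TSS was 23 of 54 (42.6%, 30.3 to 55.8). Such sites stood at the TSS of 38 of 21938 protein-coding genes (0.173%), too few for the fixed lists, in which 0 genes had one, to be read. The number of sites depends on the CTCF list being far longer than the cohesin lists: it was 1622 with lists of equal length. With a −log10 q of at least 10 in all lists it was 7. That cutoff also removes weak cohesin peaks, and 7 of the 76 sites reached it in the SMC1 list.

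In whole limbs 66.4% (65.9 to 66.9) of 33707 RAD21 peaks overlapped a peak of the whole-limb CTCF list, against 1.10% after shifting. The strongest decile did so in 99.9% and the weakest in 8.48%. The whole-limb CTCF list (43533 peaks) is shorter than the distal one (69495 peaks), so this share and that of distal forelimb are not on equal terms. RAD21 peaks without a peak in any of the 3 wild-type CTCF lists numbered 7994. Of these, 966 (12.1%, 11.4 to 12.8) lay within 1 kb of a TSS, against 8.63% (8.29 to 8.98) of the 25713 with CTCF in any of the 3. A CTCF motif was found at 6.99% (6.45 to 7.57) of the peaks without CTCF and at 80.8% (80.3 to 81.2) of those with it. The strongest at a TSS stood at Mynn (62.7), Knl1 (58.9), a kinetochore protein gene, Prmt5 (58.3), an arginine methyltransferase gene, and Polg (51.3), which encodes the mitochondrial DNA polymerase. At HoxD, Lnpk and Hoxd9 had such a peak at their TSS, but a weak whole-limb CTCF peak (74578292 to 74578574, −log10 q 2.07) lay just beside the one at Lnpk (74578628 to 74579128). A CTCF peak lay within 1 kb of 1012 of the 7994 peaks, including the one at Mynn, and without these the share at a TSS was 10.2% (9.54 to 10.96). This set was examined after seeing the data. The distal and whole-limb RAD21 lists come from different strains and tissues, and the labels give 10 or 25 minutes of fixation for RAD21 without saying which sample had which.

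**Figure D3:**
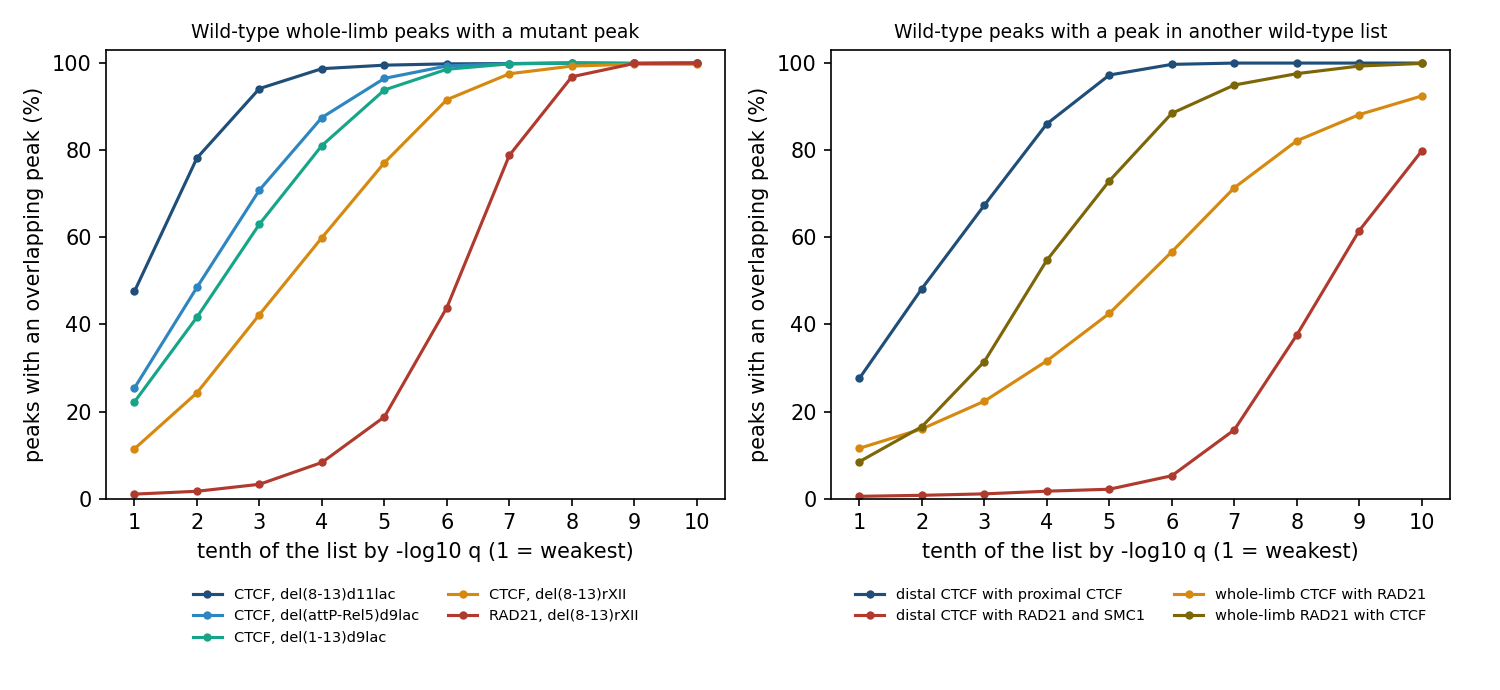
Share of peaks with an overlapping peak in another list (vertical axis, %) by decile of the authors' −log10 q within the first list (horizontal axis, 1 is the weakest). The left panel gives wild-type whole-limb CTCF or RAD21 peaks with a peak in each allele, and the right panel wild-type lists against each other. Every curve is higher in the strongest decile than in the weakest, and RAD21 in del(8-13)rXII starts at 1.04%. The CTCF curves of the lac alleles dip slightly between deciles 8 and 9, from 100% to 99.93% in del(8-13)d11lac and 99.91% in both d9lac alleles.

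Of the 17 gene lists fixed before the data were examined, distal limb patterning and housekeeping genes stood farthest above random lists of protein-coding genes of the same lengths when peaks within 10 kb were counted, an order that changed with other settings. As many members with a distal CTCF peak were found in 0.0800% and 1.23% of random lists for these, and in at least 5.33% for each of the other lists. A distal CTCF peak within 10 kb was found at 80.1% of 21938 protein-coding genes and a proximal one at 81.1%. All 27 distal limb patterning genes, among them Hoxa13, Hoxd13, Hoxd12 and Msx1, had a distal peak, where random lists gave a mean of 20.96 (percentile 99.96), and 26 had a proximal peak (percentile 99.4). With peaks inside the gene alone, 18 of these genes had a distal peak (percentile 95.7) and 16 a proximal one (76.4). Of 22 proximal limb patterning genes, 20 had a distal (percentile 89.2) and 21 a proximal peak (96.6), including Meis1 and Meis2. All 17 chondrogenesis genes, which make and shape cartilage, had a peak in both parts (percentiles 97.3 and 96.7), among them Sox9, Sox5, Sox6 and Col2a1. So had all 15 housekeeping genes, such as Actb, Gapdh, Tbp and Hprt (99.4 and 99.2), and all 11 surface ectoderm genes, such as Krt5 and Krt14 (94.97 and 94.4). The same held for the 6 forelimb and hindlimb identity genes, among them Tbx5, Tbx4 and Pitx1 (89.6 and 88.6), and for the 15 genes of the cohesin and CTCF machinery (87.9 and 87.0). At the HoxD locus 16 of 18 matched genes had a distal peak (percentile 90.6) and 16 a proximal one (89.0), and Hoxd1 and Mtx2 had neither. The HoxA cluster had 10 of 12 in both parts (90.5 and 88.4) and the HoxB cluster 9 of 10 (93.0 and 92.3). In the HoxC cluster 7 of 9 genes had a distal peak and 8, with Hoxc13 added, a proximal one (61.8 and 84.2).

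Muscle genes such as Pax3, Pax7 and Myf5 had a peak in 13 of 14 in both parts (percentiles 93.0 and 91.8), and neural genes such as Sox10 and Foxd3 in 11 of 12 (88.4 and 85.9). Endothelial genes such as Pecam1 and Cdh5 had one in 10 of 12 (37.7 and 34.1). Blood genes such as Klf1 and Tal1 had a distal peak in 10 and a proximal one in 11 of 13 (46.9 and 69.6). Genes of imprinted clusters such as Igf2 and Kcnq1 had one in 16 of 17 (89.0 and 86.4), and those of the protocadherin clusters, such as Pcdha1 and Pcdha6, in 16 of 18 (61.5 and 59.0). For distal peaks inside the gene alone, protocadherin genes stood at percentile 98.5, above distal limb patterning genes, while housekeeping genes stood at 99.8, endothelial genes at 87.3, proximal limb patterning genes at 64.5 and identity genes at 47.3. With random lists not matched on length, chondrogenesis genes (98.9) and the cohesin and CTCF machinery (98.3) stood above housekeeping genes (98.2) and below distal limb patterning genes (99.9). A list with a peak at every gene can rise no further, which limits the percentile of short lists. Percentiles come from 10000 random lists and describe these libraries alone, and genes of a cluster share peaks, which random lists do not reflect.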

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

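Of the tests here, autosomes alone, runs that pass over 1 kept site, flanks of the outermost lost sites and no CTCF peak within 1 kb were chosen after the results were seen. The comparisons fixed in advance were recomputed with 1 choice changed at a time. Sites with a −log10 q of at least 50, CTCF sites without RAD21 and the same-strand run were not recomputed, whole-limb RAD21 without CTCF only with no CTCF peak within 1 kb, and peaks of a single forelimb part only near distal limb patterning genes. No paired analysis was possible because each group has 1 library.

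The run of CTCF sites lost at HoxD stayed within 1.5 times its number of sites in each allele under every alternative fixed in advance. Passing over 1 kept site lengthened it to 5 in del(1-13)d9lac.

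The same −log10 q is not an equal cutoff across lists, whose medians differ. With a −log10 q of at least 10 in all lists, distal CTCF peaks had a proximal peak in 91.4% and proximal peaks a distal one in 91.8%. Whole-limb CTCF peaks had a distal peak in 99.4% and a proximal one in 99.2%. CTCF was found at 99.3% of distal RAD21, 98.6% of SMC1 and 86.0% of whole-limb RAD21 peaks, SMC1 at 78.6% of RAD21 peaks and both subunits at 17.2% of distal CTCF peaks. Cohesin sites without CTCF fell to 7, and with no CTCF peak within 1 kb they numbered 54. In the flanks of the unbroken run, fixed in advance, 33.3% of CTCF sites were kept in del(8-13)rXII, against 68.8% with the lists as deposited, and new peaks numbered 2 in del(8-13)d11lac, 0 in del(8-13)rXII and 0 in del(1-13)d9lac. The cause was not tested.

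Lists of equal length keep the strongest peaks alone, which by construction removes the weak peaks of the longer list. Distal CTCF peaks then had a proximal peak in 81.8%, and proximal peaks a distal one in 81.4%. Whole-limb CTCF peaks had a distal peak in 84.9% and a proximal one in 84.7%. CTCF was found at 70.0% of distal RAD21, 77.3% of SMC1 and 62.3% of whole-limb RAD21 peaks, SMC1 at 76.6% of RAD21 peaks and both subunits at 61.4% of distal CTCF peaks. Cohesin sites without CTCF rose to 1622. In the same flanks 84.0% of CTCF sites were kept in del(8-13)rXII and 94.1% of RAD21 sites, against 68.8% and 72.0%. New CTCF peaks numbered 2 in del(8-13)d11lac, 3 in del(8-13)rXII, 7 in del(1-13)d9lac and 6 in del(attP-Rel5)d9lac, and new RAD21 peaks 1.

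With at least 50% of the peak covered, the shares were 82.0% for distal CTCF with proximal, 77.1% for proximal with distal, 91.7% for whole-limb with distal and 91.7% for whole-limb with proximal CTCF. They were 93.5% for SMC1 with CTCF, 86.7% for RAD21 with SMC1, 65.1% for whole-limb RAD21 with CTCF and 11.6% for distal CTCF with both subunits. With summits within 200 bp they were 82.3% for distal with proximal CTCF, 91.8% for whole-limb with proximal CTCF, 96.2% for RAD21 with CTCF and 93.3% for SMC1 with CTCF. On autosomes alone they were 83.1% for distal with proximal CTCF, 78.7% for proximal with distal CTCF, 88.4% for RAD21 with SMC1, 67.2% for whole-limb RAD21 with CTCF and 21.03% for distal CTCF with both subunits. The cause was not tested for these.

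New CTCF peaks numbered 0 in del(8-13)d11lac with flanks of 0.5 Mb. With flanks of 2 Mb they numbered 11 in del(8-13)d11lac, 3 in del(8-13)rXII and 2 in del(attP-Rel5)d9lac, over a longer stretch. With flanks of the outermost lost sites they numbered 1 in del(1-13)d9lac and 0 in del(attP-Rel5)d9lac, since the Hoxd9 peak then lies inside.

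With motifs within 100 bp, the strand counts on each side of HoxD stayed within 1.5 times their values. On the centromeric side they became equal, with 6 motifs on each strand. Of the gene list percentiles, 13 moved with unmatched random lists and 16 with peaks within the gene alone. For distal peaks, unmatched lists took the HoxA cluster to 57.1, endothelium to 58.4 and the cohesin and CTCF machinery to 98.3. Peaks within the gene took endothelium to 87.3, protocadherin clusters to 98.5, muscle to 66.6, proximal limb patterning to 64.5, forelimb and hindlimb identity to 47.3, neural to 44.2 and the HoxC cluster to 11.1. The cause was not tested. Read depth is unknown, so the loss of weak sites in del(8-13)rXII cannot be set against the depth of its library.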

Other observations

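All tests of peaks inside the HoxD interval, of the sites between Evx2 and Hoxd13, of the calling threshold for distal-only peaks and of CTCF peaks within 1 kb were chosen or changed after the results were seen; the tests of the motif and of shared CTCF peaks were set before their results, on a pattern that had been seen.

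The lac alleles held CTCF peaks inside their lost intervals, at Hoxd9 and in Hoxd10 in both d9lac alleles and before Hoxd11 in del(8-13)d11lac. Wild-type DNA in the mutant libraries would bring the stronger sites too, and at least 4 stronger wild-type sites of the interval had no peak in each d9lac list. Whether reporter gene sequence in the allele carries the new peaks stays open. All 3 were nearest to the gene the reporter is named after, but both at Hoxd9 are the same place. The Hoxd10 peak is nearest to another gene, but the wild-type summit there lies 3490 bp before Hoxd9, so this does not speak against the reporter. By its name del(1-13)d9lac lacks Hoxd9 and Hoxd10. A called peak does not tell sequence left in place from sequence carried with the reporter. The Hoxd9 peaks overlap a weak wild-type whole-limb RAD21 peak (−log10 q 6.25), and no biological explanation was tested.

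The RAD21 site between Evx2 and Hoxd13 at 74661724 to 74662200, without a peak in del(8-13)rXII, is not accounted for by the shorter mutant RAD21 list, because 0 of 3199 peaks at least as strong lacked a mutant peak (0%, up to 0.120%). The site was weak within the distal forelimb list (−log10 q 5.80, median of the list 14.2); of 8 whole-limb peaks at least as strong and as weak there, 0 lacked a mutant peak (up to 32.4%), and in a wider set of peaks of at least 50% of its strength, taken after that, 2 of 158 did (1.27%, 0.348 to 4.50). A gapless deletion that reaches the site is argued against by 1 kept RAD21 site between it and Hoxd13. For the CTCF peak at the same place, a weaker mutant library could be enough, since 29.8% (28.5 to 31.2) of 4164 sites of like strength also lacked a peak in del(8-13)rXII. A change at this site in the allele, or a difference in fixation between the RAD21 libraries, was not tested and stays open.

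Distal-only CTCF peaks lay within 10 kb of 11 of 27 distal limb patterning genes, among them Hoxa13, Shh, Grem1 and Wnt5a, against 5.43 in random lists (percentile 99.5), 1 of 34 list and measure pairs read. Whether many CTCF peaks common to both forelimb parts near these genes are enough stays open: random lists matched on their number gave 6.998 genes, and the list stood at percentile 95.6, past the limit of 95 set before, but 6.20% of random lists were as high, so the excess is not beyond their spread. A match on all distal peaks (percentile 87.2) counts the tested peaks too and decides nothing. Peaks near the calling threshold also stay open, since with a −log10 q of at least 10 only Hoxa13 and Lhx2 were left, against 0.579 in random lists (percentile 93.5). Signal without a motif was tested with a motif at 58.3% (32.0 to 80.7) of 12 peaks and 42.3% of the others. By the limit set before, an interval that reaches the share of the others goes against it. With 12 peaks the interval also spans lower shares, so this was left open. The distal-only peaks at Hoxa13, Shh, Grem1 and Wnt5a overlapped no whole-limb CTCF peak, while 1 at Ptch1 did. Of all distal-only peaks 4.51% overlapped one, against 68.4% of shared distal peaks. Proximal-only peaks lay near 8 of 22 proximal limb patterning genes, against 8.21 in random lists (percentile 46.1). The difference between the tissues stays open, as untested.

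Proximal-only CTCF peaks lay near 3 of 18 protocadherin genes, against a mean of 7.81 in random lists (percentile 0.490), and distal-only peaks near 7 (percentile 55.3). Neighbouring genes of this cluster share peaks, which random lists do not reflect. The CTCF list of del(8-13)rXII had a motif at 52.1% (51.6 to 52.6) of its peaks, against 73.3% to 85.8% in the other CTCF lists. Whole-limb RAD21 peaks without CTCF stood at the TSS of 3 of 18 genes of the HoxD locus (Lnpk, Hoxd9 and Nfe2l2), at percentile 98.0, but with no CTCF peak within 1 kb only that at Hoxd9 was left, at percentile 72.4.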
